A study of Mus musculus with 19 samples.

How the data were processed

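Capture Hi-C of the Shh locus was made from E10.5 mouse limb buds and midbrain and from ES cells. Per the labels' protocols, tissue was dissociated with collagenase, fixed with formaldehyde, cut with DpnII, ligated, sheared, and enriched with custom SureSelect probes before paired-end sequencing. The submitters' processing notes name cutadapt 1.15, Bowtie2 2.3.4.1, Juicer, SAMtools and the mm9 build. Settings of these tools and the handling of duplicate read pairs are not given in the sources used here. The deposited values are a signal per pair of 10 kb bins, 1 map per group with its samples merged and balanced (KR) by the authors, per the names of the deposited files. Balancing divides each count by a factor of both bins so that every bin has the same total. In the files bin totals were equal within each map and ranged from 7602 to 20135 between maps, so signal was not compared between maps without scaling. Pairs with no signal are not listed and were taken as 0. Because libraries were merged before deposit, no spread between replicates could be computed, and no test or p-value is given. Per the series design, wild type samples are biological replicates and mutant samples technical ones. By their titles, 2 of the 3 wild type limb samples share a library number, so they may not be separate libraries. The title of 1 ES cell sample and the name of its merged map differ in the suffix of the library number.

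Each map was read as a matrix of 280 bins (39340 possible pairs, 38067 to 39065 listed). Observed over expected is the signal over the mean signal at the same separation in the same map, zeros included. The Shh promoter is the 2 bins that overlap the viewpoint in the labels (28789001 to 28799000), with distances counted from the bin that holds 9000 bases of it. The ZRS window is the 5 bins from 830 to 870 kb, placed from general knowledge that the ZRS lies about 850 kb from Shh. Contact is the mean over the 10 bin pairs, and a ratio between maps is the log2 of the ratio of contacts, over 11 comparisons fixed in advance. Each was set beside the same block moved along the diagonal. The first run left out only the target block (191 blocks). After its values were seen, blocks sharing any upper bin with the target were left out as well (183 blocks). This change lowered the percentile of the CTCF ratios to wild type from 0.524 to 0 and narrowed the SD over blocks, for limb i4i5 from 0.35 to 0.29, and raised the percentile of the contact itself to 100 from 96.3 in that map, from 98.4 in i4i5 plus ZRSreg and midbrain i4i5ZRS and from 98.95 in the others, except ES cells, where it was 100 with both.

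Insulation is the log2 of the mean signal in a 10 by 10 bin square across a bin over its mean along the map. The borders were the minima of its mean over all 9 maps within 100 kb of the promoter and from 800 to 1000 kb above it. Domain contacts used bins between the borders, separations of 50 kb or more within the domain, and the 500 kb above the upper border. The domain interior was 100 to 750 kb. The share of promoter contacts used separations of 20 kb or more. Maps were compared by rank correlation at 50 to 1500 kb. Named features, fixed before the data were examined, were Shh, the ZRS window and Lmbr1, the peak bin of each promoter profile beyond 500 kb, both border bins, and in each comparison the 3 highest and 3 lowest bin pairs of a 5 by 5 bin mean at 100 kb or more, at least 50 kb apart. The bin pairs printed are a selection of these, made after their values were seen, and the rest are given as counts. A gene table of another build (GRCm38.p6) was used for gene order only, with Lmbr1 the second protein-coding gene after Shh, so no gene is placed at a bin.

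Balanced values are a whole count over 2 bin factors. This was noticed after the data were seen and used to recover contact counts, 100% of them within 0.01 of a whole number in every map. Counting intervals are exact Poisson or binomial intervals (95%; Wilson for shares) of those counts, scaled to the balanced value. They hold for counting error only, since pairs without molecular identifiers are not independent molecules. Other choices made after the data were seen are the coverage checks, the contact of the promoter with the upper flank, the limb against midbrain scan of the promoter profile, the bin of the largest insulation rise, and the spreads by which an alternative counts as moved. On simulated maps of the limb i4i5 over wild type limb comparison (20 simulations, 39340 pairs), a true Shh-ZRS log2 ratio of -1.02 was recovered at a mean of -1.00 (SD 0.11) and a cross-border ratio of 0.25 at 0.23 (SD 0.01). With no change the means were 0.00 for both. In 3 simulated maps 100% of counts were recovered.

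Alternatives fixed in advance were the median for the expected value, no scaling or total scaling, other windows, viewpoint bins, square sizes, flanks, separations, smoothing and G4 reference maps. Added later were counts without balancing and counts thinned to the shallowest map (1177173). The first set of shifted blocks is kept as an alternative to the main set, which was chosen after it. The coverage check against 6 neighbouring bins was the last of 3 versions looked at. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.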

Results

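Contacts along the mouse Shh locus were measured by capture Hi-C, in which DNA ends joined by ligation in fixed nuclei are enriched for 1 genomic region and sequenced as pairs. Shh encodes the secreted signal Sonic hedgehog, which patterns the limb bud and the nervous system, and its limb enhancer, the ZRS, lies far away within an intron of the gene Lmbr1. The 19 samples fall into 9 groups. Wild type limb buds have 3 samples, and each of the other groups has 2: wild type midbrain, wild type embryonic stem (ES) cells, limb buds with 5 different deletions, and midbrain with 1 of those deletions. The embryos were at day E10.5. The deletions are of CTCF sites named i4 and i5 (i4i5), of these and a further CTCF site named for the ZRS (i4i5ZRS), of an element named ZRSreg, of i4, i5 and ZRSreg together, and of the Lmbr1 promoter. CTCF is a DNA-binding protein found at many chromatin loop anchors and domain borders. Each group was deposited as 1 merged map in 10 kb bins, so no value below has a replicate error and no p-value is given.

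The maps cover 280 bins of chromosome 5 from 27800001 to 30600000 in the mm9 build. Total contact counts, recovered from the balanced signal, were 2862106 in wild type limb, 2201297 in wild type midbrain, 3218492 in ES cells, 1177173 in limb i4i5, 1983686 in limb i4i5ZRS, 2544793 in limb ZRSreg, 2530300 in limb i4i5 plus ZRSreg, 3022706 in the Lmbr1 promoter deletion and 2144694 in midbrain i4i5ZRS. Values are given as observed over expected, the balanced signal divided by the mean signal of all bin pairs at the same separation in the same map. The Shh promoter was represented by the 2 bins from 28780001 to 28800000 and the ZRS window by the 5 bins from 29620001 to 29670000, 830 to 870 kb from the main promoter bin. Intervals are 95% intervals that cover counting error only and compare these libraries, not the conditions.

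The first comparison asked whether the promoter and the enhancer region touch in tissues other than limb. They did so at a like level in all 3 wild type maps. The Shh promoter met the ZRS window at 6.49 times the expected signal in limb (counting interval 6.17 to 6.82, 1574 contacts), at 6.61 in midbrain (6.23 to 7.01, 1115 contacts) and at 6.77 in ES cells (6.35 to 7.20, 1001 contacts). The SD over the 10 bin pairs was 1.24, 1.65 and 1.59. On the log2 scale midbrain stood 0.03 above limb (-0.09 to 0.14) and ES cells 0.06 above limb (-0.06 to 0.18), both within the SD of 0.25 and 0.49 seen when blocks of the same size were compared at the same separation elsewhere in the region. The sign of these small differences changed with the setting, the ES cell value being -0.41 under total scaling. Among 183 such blocks the highest value was 3.26 in limb, 3.26 in midbrain and 3.00 in ES cells. None of these blocks lay wholly within the Shh domain, whose borders were at -30 and 910 kb, so they are no measure of other contacts inside it. When shifted blocks that overlap the target were kept, 189 of 191 were lower than the target in limb and in midbrain, and all 191 in ES cells.

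The 3 wild type maps differed at other places. In limb and midbrain the highest promoter contact beyond 500 kb lay 810 kb away (29600001 to 29610000), at 7.88 and 9.56. ES cells shared this peak among bins below 900 kb, at 9.12. Their highest contact beyond 500 kb lay 1010 kb away (29800001 to 29810000), beyond the upper border of the domain, at 13.1 against 5.42 in limb. The log2 ratio at that bin, 1.27 (1.05 to 1.497), was above all shifted blocks. Despite this peak, the share of promoter contacts beyond 1000 kb was lower in ES cells (7.12%, 6.84% to 7.41%) than in limb (10.99%, 10.7% to 11.3%) or midbrain (10.3%, 9.93% to 10.7%). Contact between the Shh domain and the 500 kb above it was 0.570 in ES cells against 0.715 in limb, a change of -20.3%. The log2 ratio of -0.33 lies within its SD of 0.43 over the flanking bins, of which 13 of 50 were higher in ES cells. The lower border, the bin 28760001 to 28770000, was deeper in ES cells, with an insulation of -1.55 against -1.04 in limb and -1.12 in midbrain. The difference of -0.51 to limb was -0.19 with a square of 5 by 5 bins. The pairs of bins with the largest falls from limb to ES cells joined the bin 1290 kb above the promoter to bins of the domain interior at 330, 450 and 540 kb, with log2 ratios of -1.85, -1.63 and -1.53.
The pair with the largest rise joined the bin 360 kb below the promoter to the bin 20 kb below it (1.82 in ES cells, 0.876 in limb, log2 ratio 1.05), and the next joined bins 280 and 130 kb below it (1.45 against 0.784).

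**Figure D1:**
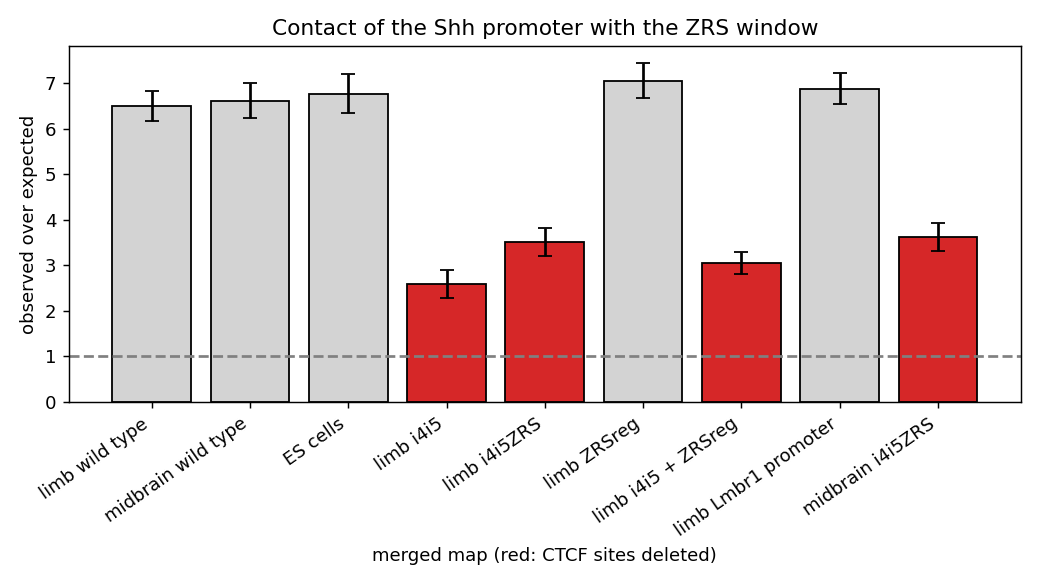
Observed over expected contact between the Shh promoter and the ZRS window in each of the 9 merged maps, with 95% counting intervals as error bars and the dashed line at 1, the value expected at this separation. The 5 maps without CTCF deletions lie between 6.49 and 7.05 and the 4 maps with them between 2.58 and 3.62.

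The second comparison asked what the CTCF sites contribute. In every map that lacked i4 and i5, contact between the Shh promoter and the ZRS window was lower than in wild type, and it still exceeded the value expected at that separation. It was 2.58 in limb i4i5 (2.29 to 2.90, 285 contacts), 3.51 in limb i4i5ZRS (3.21 to 3.82, 506 contacts) and 3.05 in limb i4i5 plus ZRSreg (2.81 to 3.30, 620 contacts), against 6.49 in wild type limb. The contact fell by 60.2%, 46.0% and 53.0%, or log2 ratios of -1.33 (-1.52 to -1.15), -0.89 (-1.04 to -0.74) and -1.09 (-1.23 to -0.96). In midbrain the i4i5ZRS deletion gave 3.62 (3.32 to 3.94, 538 contacts) against 6.61 in wild type, a log2 ratio of -0.87 (-1.02 to -0.72). None of the 183 shifted blocks had as low a ratio in any of these 4 comparisons. As no such block lay wholly within the Shh domain, this rank does not set the loss against other pairs inside it. It cannot show that the loss is particular to the promoter and the ZRS window. When shifted blocks that overlap the target were kept, 1 of 191 was lower in each comparison. The expected value averages pairs within and across the domain borders, so exceeding it does not set the window apart from its surroundings. In all 4 maps each bin of the window had less promoter contact than the bins at 810 and 910 kb. In limb i4i5 the window bins ranged from 2.20 to 3.095, against 5.49 at 810 kb and 5.04 at 910 kb. With a wider ZRS window of 800 to 900 kb the midbrain log2 ratio was -0.52. On the signal as deposited, which is on no common scale, limb i4i5 and i4i5ZRS gave -2.49 and -1.60.

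Within the region around the ZRS the loss was uneven. At 820 kb (29610001 to 29620000) the log2 ratio to wild type was -1.10 in limb i4i5, -1.04 in limb i4i5ZRS, -1.02 in limb i4i5 plus ZRSreg and -0.96 in midbrain i4i5ZRS. At 810 kb, the neighbouring bin and the peak of the wild type profile, it was -0.52, -0.35, -0.44 and -0.25. These falls at 810 kb lay at the 8.8, 13.5, 7.3 and 24.9 percentile of shifted blocks, each within its SD over them. Those at 820 kb lay at the 0.52 to 1.04 percentile. The highest promoter contact beyond 500 kb in the 3 limb maps lay at 1010 kb, at 7.34, 7.98 and 8.82 against 5.42 in wild type limb. The gain at that bin itself, a log2 ratio of 0.44 (0.16 to 0.71), 0.56 (0.30 to 0.82) and 0.70 (0.48 to 0.93), exceeded counting error but lay at the 79.1, 84.4 and 94.2 percentile of the shifted blocks. In midbrain i4i5ZRS the peak lay at 810 kb, at 8.06, and at 790 kb when the main promoter bin was used alone. There the promoter's contact with the upper border bin at 910 kb (29700001 to 29710000) was 7.15 against 3.37 in wild type midbrain (log2 ratio 1.08, 0.67 to 1.51, 155 and 71 contacts, 97.8 percentile of shifted blocks). The same bin gave 6.34 in limb i4i5ZRS against 4.27 in wild type limb (0.57, 0.22 to 0.92), at the 80.9 percentile. In limb i4i5 and i4i5 plus ZRSreg the ratio at that bin was 0.24 (-0.19 to 0.66) and 0.25 (-0.09 to 0.59), intervals that include 0.

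**Figure D2:**
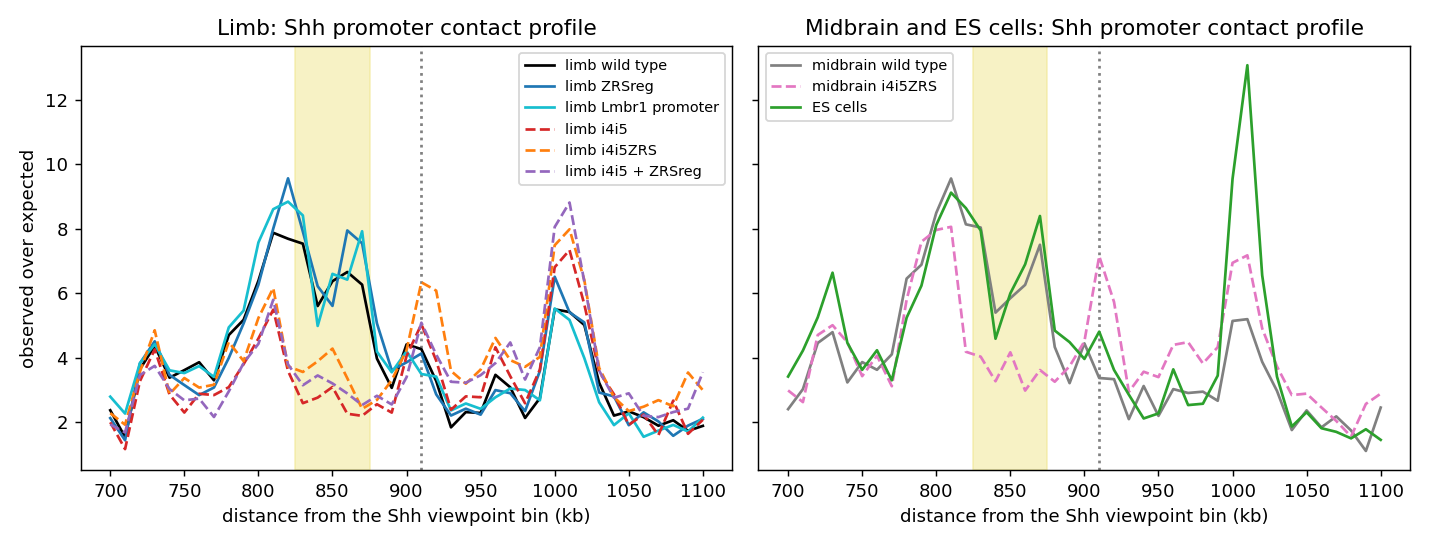
Observed over expected contact of the Shh promoter with each 10 kb bin from 700 to 1100 kb above it, for the limb maps and for the midbrain and ES cell maps, 1 line per merged map, dashed where CTCF sites are deleted. The band is the ZRS window and the dotted line the upper border bin at 910 kb. The dashed lines lie below the wild type lines in the band, and the ES cell line reaches 13.1 at 1010 kb.

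The contacts lost at the ZRS were accompanied by more contact beyond the domain. The share of promoter contacts beyond 1000 kb was 16.0% (15.4% to 16.6%) in limb i4i5, 15.4% (14.9% to 15.9%) in limb i4i5ZRS and 16.3% (15.9% to 16.7%) in limb i4i5 plus ZRSreg, against 10.99% in wild type limb, and 13.7% (13.2% to 14.1%) in midbrain i4i5ZRS against 10.3% in wild type midbrain. Contact between the whole Shh domain and the 500 kb above it was 26.3%, 24.8% and 23.6% higher in the 3 limb maps and 26.2% higher in midbrain i4i5ZRS, with all 50 flanking bins higher in each. Contact within the domain changed by -11.6%, -6.66% and -8.70% in limb and by -4.42% in midbrain. The ZRS window itself had 25.6%, 19.5% and 14.3% more contact with the upper flank in limb and 17.9% more in midbrain. Its contact with the domain interior changed by -16.2%, -11.5% and -10.1% in limb and by -7.49% in midbrain. The changes across the border exceeded their SD over bins in all 4 maps. Those within the domain in i4i5ZRS lay within it, with 14 of 93 bins higher in limb and 22 of 93 in midbrain. So did those of the ZRS window with the flank in i4i5 plus ZRSreg (42 of 50 higher) and in midbrain (45 of 50). With the interior, those in limb i4i5ZRS, i4i5 plus ZRSreg and midbrain i4i5ZRS lay within it (17, 16 and 18 of 66 higher). This SD describes single bins, which are not independent, and is not an error of the mean. Insulation at the upper border, where less negative values mean more contact across it, was -0.78 in wild type limb, -0.52 in i4i5, -0.62 in i4i5ZRS and -0.62 in i4i5 plus ZRSreg. The differences of 0.26, 0.16 and 0.17 compare with SDs of 0.08, 0.08 and 0.09 over 260 bins. In midbrain insulation was -0.56 in the mutant and -0.68 in wild type, whose own minimum lay at 890 kb (-0.71). The largest rises among the 260 bins lay not at this bin but below it, at 880 kb in limb i4i5 (0.43) and i4i5ZRS (0.38) and at 860 kb in i4i5 plus ZRSreg (0.35) and midbrain i4i5ZRS (0.37). With a square of 5 by 5 bins the difference at the border bin was 0.03 in midbrain and 0.14 in limb i4i5. At the lower border midbrain i4i5ZRS was more insulated than wild type midbrain, -1.31 against -1.12, and the difference of -0.19 was the lowest of the 260 bins. In the limb maps with CTCF deletions the difference there was 0.09 in i4i5, -0.04 in i4i5ZRS and 0.06 in i4i5 plus ZRSreg.

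**Figure D3:**
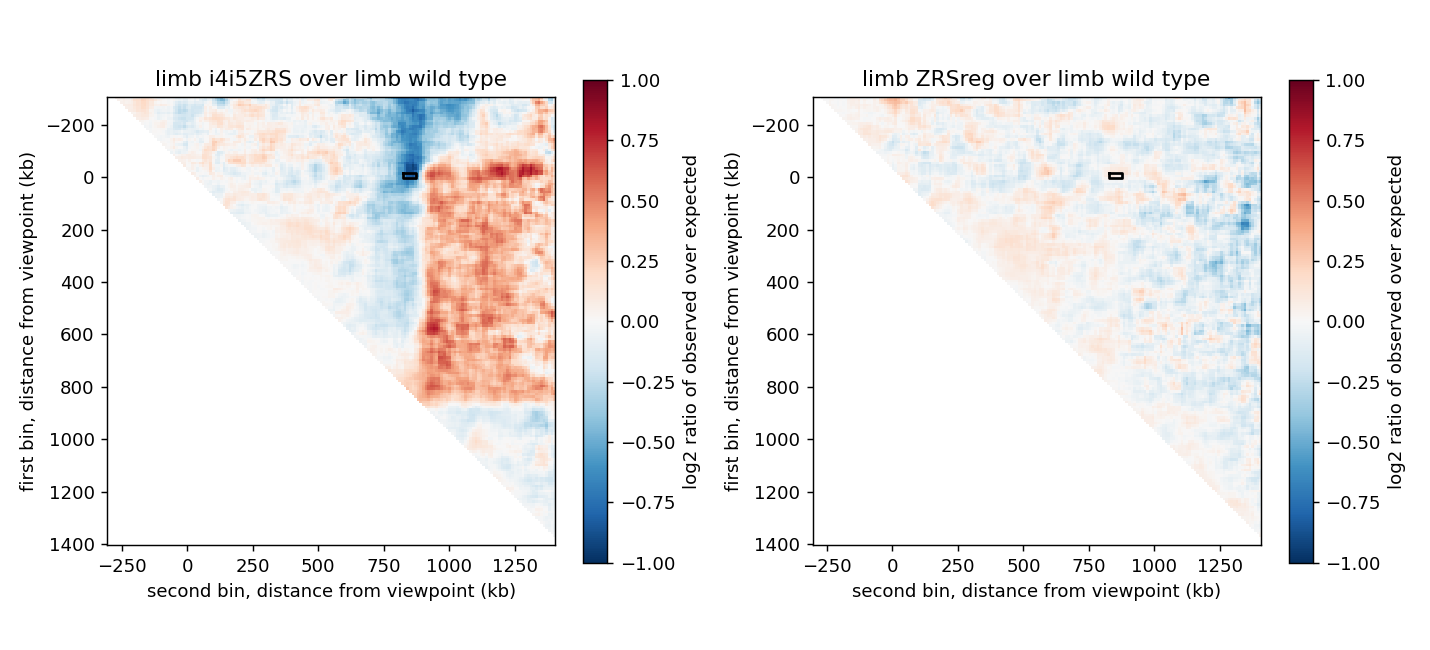
Log2 ratio of observed over expected to wild type limb for limb i4i5ZRS and limb ZRSreg, after a 5 by 5 bin mean, for bin pairs around the promoter (axes in kb from it), with the Shh promoter against ZRS window boxed. In i4i5ZRS the box is blue and the block between the domain and the bins beyond 910 kb red, which is the 24.8% gain, while ZRSreg shows neither.

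The third comparison asked what the ZRSreg element and the Lmbr1 promoter contribute. On the main measure the contact did not fall in either. The Shh promoter met the ZRS window at 7.05 in limb ZRSreg (6.67 to 7.44, 1288 contacts) and at 6.87 in the Lmbr1 promoter deletion (6.54 to 7.21, 1615 contacts). The log2 ratios to wild type were 0.12 (0.01 to 0.23) and 0.08 (-0.02 to 0.18), inside the SDs of 0.20 and 0.21 over shifted blocks. The sign of both depended on the setting. Their promoter profiles peaked at 820 kb, at 9.56 and 8.84. Contact across the upper border changed by -4.83% and 2.05%, within the SD over the flanking bins. The Lmbr1 promoter deletion had a less negative insulation at the upper border, -0.59 against -0.78 in wild type. The difference of 0.19 was the largest rise among the 260 bins of that comparison. It was smaller than the largest rise in each CTCF comparison with wild type, but those lay at other bins. At the border bin itself it exceeded limb i4i5ZRS (0.16), limb i4i5 plus ZRSreg (0.17) and midbrain i4i5ZRS (0.12), but not limb i4i5 (0.26). Contact of the Lmbr1 promoter map across the border bin at 910 kb was within 2.05% of wild type. That mean spans the whole domain and the 500 kb above it, and takes in the square used for insulation. In that map this border bin also had the lowest recovered coverage of 274 bins against its 6 neighbours (log2 -0.27), and a link between both was not tested. In ZRSreg the insulation there was -0.82.

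**Figure D4:**
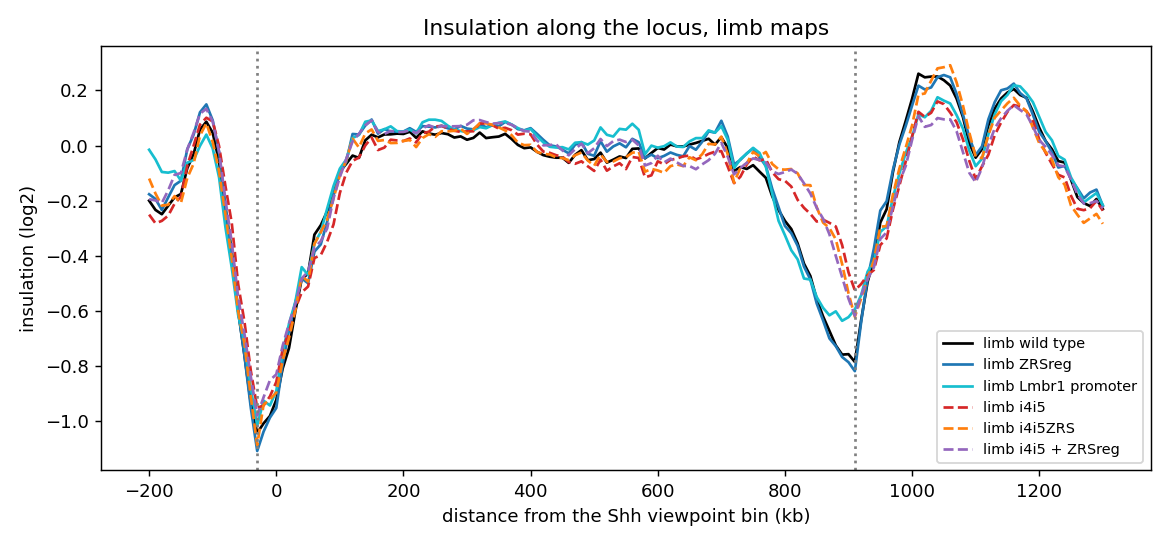
Insulation (log2 of the mean signal in a 10 by 10 bin square across each bin over its mean along the map) plotted by distance from the promoter in kb, 1 line per merged limb map, dashed where CTCF sites are deleted. Dotted lines mark the borders at -30 and 910 kb, and the 3 dashed lines and the Lmbr1 promoter line are less negative at 910 kb than wild type (-0.78).

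Alleles that combine deletions were compared with the single ones. Limb i4i5ZRS, which lacks a further CTCF site, had more rather than less promoter contact with the ZRS window than limb i4i5, with a log2 ratio of 0.44 (0.23 to 0.65) at the 98.9 percentile of shifted blocks. In limb i4i5 the recovered counts over the bins from 860 to 900 kb were low against their flanks (log2 -0.33), which was not so in the other maps (-0.03 to 0.08). Of these, the bins at 860 and 870 kb belong to the ZRS window. At 830, 840 and 850 kb, outside the low bins, promoter contact in limb i4i5 was 2.59, 2.77 and 3.095. In wild type limb it was 7.54, 5.61 and 6.38. Limb i4i5 plus ZRSreg stood 0.24 (0.03 to 0.45) above i4i5, at the 87.4 percentile of shifted blocks, whose SD was 0.23. Its log2 ratio to ZRSreg alone was -1.21 (-1.35 to -1.07). The combined allele departed from the sum of both single log2 changes by 0.12, with a counting standard error of 0.12 and an SD of 0.26 over shifted blocks. On the signal as deposited this value was 1.31, and the ratios of i4i5ZRS and of i4i5 plus ZRSreg to i4i5 were 0.89 and 1.21.

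Across whole maps the rank correlation of observed over expected over 28654 bin pairs, which are not independent replicates, was 0.756 to 0.768 among limb maps without CTCF deletions, 0.577 to 0.702 between limb maps with and without them, and 0.565 to 0.650 among limb maps with them. These values may also depend on depth, and limb i4i5, the shallowest map, had the lowest ones. Among the bin pairs with the largest changes, the pair joining the bins 20 kb below and 850 kb above the promoter bin stood among the 3 largest falls in limb i4i5 (2.81 against 6.22, 450 and 2333 contacts) and was the largest fall in i4i5 plus ZRSreg (3.06 against 6.22). In i4i5ZRS the pair joining bins at -330 and 880 kb was among the 3 largest falls in both tissues, at 0.750 against 1.54 in limb and 0.787 against 1.53 in midbrain. Midbrain i4i5ZRS also had the pair at -260 and 860 kb (0.842 against 1.54) and limb i4i5 plus ZRSreg the pair at -150 and 850 kb (1.38 against 2.51) among their 3 largest falls. The largest rise in i4i5 plus ZRSreg joined the promoter bin to the bin at 1660 kb (1.40 against 0.679, 369 and 193 contacts), and that in limb i4i5ZRS joined bins at -20 and 1590 kb (1.66 against 0.743, 100 and 75 contacts). Of the 66 top pairs of all 11 comparisons, 47 held under 100 contacts in at least 1 map, among them all 12 of the ZRSreg and Lmbr1 promoter deletions and 13 of the 24 in the 4 CTCF comparisons with wild type.

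By the labels, wild type limb and midbrain were C57BL/6 and all mutants and the ES cells G4. Strain and genotype are therefore confounded in each comparison of a mutant with wild type, and strain and cell type in that of ES cells with limb. Against the G4 limb maps of ZRSreg and the Lmbr1 promoter deletion in place of wild type, the log2 ratios of the 3 limb CTCF maps stayed between -1.45 and -0.97. The wild type and i4i5 libraries also carry earlier library numbers than the other groups.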

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

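All tests in this part were chosen after the result was seen. Recovered counts per bin, which balancing hides and which are not the main measure, were low in limb i4i5 from 860 to 900 kb. Of these 5 bins, those at 860 and 870 kb belong to the ZRS window. The 5 bins had a log2 value of -0.33 against their flanks, with 20.6% of the coverage missing. The other 8 maps ranged from -0.03 to 0.08, and 3 of 265 runs of 5 bins were lower in the i4i5 map. The deficit is -33.0 counting standard errors, which argues against independent counting noise alone. That error (0.0101) is small beside the SD of 0.095 over runs of 5 bins in this map. The number of errors therefore does not set this segment apart from other runs. The wild type maps of the same library number range were at 0.01 and 0.02, the more negative being 0.0130. These values argue against a bias shared by that series. Loss of the segment from part of the alleles may be weighed through contact between its flanks, which was 0.846 (0.755 to 0.945) against 1.29 computed for such a loss (a difference of -0.444), while of the other limb CTCF maps i4i5ZRS, at 0.76, lies in that interval and i4i5 plus ZRSreg, at 0.684, below it. The computed value assumes the map's mean decay with distance, so this stays open, as does a fault of this library alone, which has no replicate here.

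The promoter's gain with the upper flank, 0.26 to 0.54 on the log2 scale in the 4 CTCF comparisons and in limb i4i5 within its SD of 0.39 over flank bins, was weighed against strain, balancing and the border as a whole. The G4 limb maps without CTCF deletions changed by -0.0219 and -0.04, which argues against strain in limb. Contacts with the domain interior changed by -0.23 in limb i4i5, -0.0166 in limb i4i5ZRS, -0.21 in limb i4i5 plus ZRSreg and 0.06 in midbrain. None of these exceeded the largest SD over interior bins, 0.24. The smallest lead of the flank over the interior was 0.44, in midbrain, against SDs of up to 0.24 over interior and 0.42 over flank bins. Redistribution by balancing was taken to raise both alike, so this lead argues against it as the only source of the gain. How much of the gain it may add cannot be judged, because contact within the domain was lower on average in the same maps. The gain may belong to a weaker border for the whole domain, whose bins had median gains of 0.30 to 0.36. The promoter ranked at the 19.4, 97.8, 87.1 and 95.7 percentile of the 93 domain bins in limb i4i5, i4i5ZRS, i4i5 plus ZRSreg and midbrain i4i5ZRS, so a gain specific to the promoter stays open.

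The lower Shh-ZRS contact in limb i4i5 than in i4i5ZRS had a counting interval with a lower bound of 0.23, which argues against counting noise. It was not limited to the bins of low coverage, since the log2 ratio over 830 to 850 kb alone was 0.47 (0.23 to 0.72). At the 98.9 percentile of shifted blocks it is unusual along the region, but with 1 map per allele the spread between maps of 1 allele is unknown, and the difference cannot be told apart from it.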

How the results depend on the processing

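Of 440 alternative values for 136 results, 388 stayed within the spread of the main value and 52 moved. The sign was opposite to the main value in 18, of which 3 moved, each for a main value smaller than its spread, and in 0 for a main value beyond its spread. Counts without balancing and counts thinned to the shallowest map were chosen after seeing the data, and so was the main set of 183 shifted blocks, which replaced the first set of 191. Leaving out weak bins removed 0 bins, so its 20 values test nothing and are not counted. Leaving out 1 sample was not possible because the maps are merged. No paired analysis was possible because each group is 1 merged map. Where not stated, the cause was not tested. With the median taken for the expected value, Shh-ZRS contact was 8.84 in limb wild type, 8.999 in midbrain wild type, 8.75 in ES cells, 9.75 in ZRSreg, 3.55 in i4i5 plus ZRSreg, 9.25 in the Lmbr1 promoter deletion and 4.39 in midbrain i4i5ZRS, and the cross-border log2 ratio of limb i4i5 was 0.24. With a ZRS window of 800 to 900 kb, which takes in bins that lost less, contact was 3.23 in limb i4i5 and 4.53 in midbrain i4i5ZRS, and log2 ratios were -0.89, -0.62 and -0.79 for i4i5, i4i5ZRS and i4i5 plus ZRSreg over wild type limb, -0.52 in midbrain and -0.91 for i4i5 plus ZRSreg over ZRSreg. On the signal as deposited, which is on no common scale by construction, log2 ratios over wild type limb were -0.44 for midbrain, -2.49 for i4i5, -1.60 for i4i5ZRS and -0.10 for ZRSreg. Over i4i5 they were 0.89 for i4i5ZRS and 1.21 for i4i5 plus ZRSreg, and the genotype combination was 1.31. The midbrain i4i5ZRS peak moved to 790 kb with the main viewpoint bin alone. Insulation differences at the upper border with 5 by 5 bins were 0.14 for limb i4i5, 0.0289 for midbrain i4i5ZRS and 0.12 for i4i5 plus ZRSreg over ZRSreg, and with 20 by 20 bins 0.0127 for midbrain over limb wild type and 0.21 for midbrain i4i5ZRS. At the lower border they were -0.19 for ES cells and -0.0430 for i4i5ZRS over i4i5 with 5 by 5 bins, and -0.18 for midbrain over limb wild type and -0.0518 for the Lmbr1 promoter deletion with 20 by 20 bins. After a 5 by 5 bin mean, which averages counting noise, the rank correlation with wild type limb was 0.948 for midbrain, 0.899 for ES cells, 0.901 for i4i5, 0.923 for i4i5ZRS, 0.975 for ZRSreg, 0.929 for i4i5 plus ZRSreg, 0.967 for the Lmbr1 promoter deletion and 0.855 for midbrain i4i5ZRS. With a 3 by 3 bin mean, on fewer contacts per square, the largest rise and fall were 3.94 and -3.56 in i4i5, 2.94 and -2.48 in i4i5ZRS, 3.35 and -3.49 in i4i5 plus ZRSreg, 3.20 and -1.71 in ZRSreg, 3.98 and -1.58 in the Lmbr1 promoter deletion, and 3.16 and -1.82 in midbrain i4i5ZRS. Keeping overlapping shifted blocks put the ratios of the CTCF maps to wild type at the 0.524 percentile in place of 0.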

Other observations

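All values in this part were looked at after the data were seen. Coverage of recovered counts at the bin 850 kb from the promoter, against its 6 neighbours, was the lowest of 274 bins in limb ZRSreg (log2 -0.21) and ranked 5 from the lowest in i4i5 plus ZRSreg (-0.12). At the upper border bin, 910 kb away, it was the lowest of 274 in the Lmbr1 promoter deletion (-0.27). The Lmbr1 promoter map also ranked 3 from the lowest at 850 kb (-0.13) and the ES cell map 4 at 910 kb (-0.16), so these bins do not mark the deletions alone. In limb i4i5, low over the bins just above, the 850 kb bin was the highest of 274 (0.42). Its 6 neighbours take in some of those low bins, and against the other maps alone its coverage was at 0.18.

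Coverage over bins, centred on the mean of the 9 maps, correlated between limb i4i5 (G4) and the C57BL/6 wild type maps of limb (r = 0.454) and midbrain (r = 0.518), the groups with neighbouring library numbers, and negatively between i4i5 and the G4 maps of i4i5ZRS (r = -0.650) and the Lmbr1 promoter deletion (r = -0.784). With i4i5 plus ZRSreg it was 0.03. These are correlations across bins of centred values, which pull apart by construction.

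In the i4i5ZRS deletion the promoter's contact with the bin at 790 kb was lower in limb (3.90 against 5.18) and higher in midbrain (7.60 against 6.89). The difference of -0.55 between the tissues is 2.56 counting standard errors. Of the 141 bins from 100 to 1500 kb, 5 including this one differed by as many standard errors, 16 by more than 2, and 23 by as much on the log2 scale, and the signs were opposite at 45. The bin was picked after the profiles were seen, and the difference has no replicate check.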
